A study of Danio rerio with 6 samples.

How the data were processed

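RNA sequencing was used to compare zebrafish (Danio rerio) embryos of 2 genotypes at 3 days post fertilization. Each of the 6 libraries came from a pool of 10 embryos sorted by genotype, with 3 pools of wild-type (WT) embryos and 3 pools of bcas2 knockout (bcas2-KO) embryos. Per the labels, RNA was extracted with TRIzol, libraries were made with the NEBNext Ultra RNA kit, and paired reads of 150 bases were generated on a HiSeq instrument. The kit as named does not mark strand, and the strand setting of the counting is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

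The deposited raw counts are whole numbers of reads per Ensembl gene in each library. The deposited FPKM values are the authors' second table of the same genes and libraries. The submitters' processing notes name the genome build GRCz11 (danRer11) and the tools cutadapt 1.15, STAR 2.6.1a, featureCounts 1.6.0, StringTie 1.3.3b and DESeq2 1.22.1, without saying which tool made which table. The annotation release and the filters are not given in the sources used here. Within a gene, the ratio of count to FPKM was the same in every library after 1 factor per library, with a coefficient of variation of at most 0.0223% over 7169 genes. That factor lay between 0.931 and 1.06 times the column total of the counts. Per the labels, 6 Gb were sequenced per library, which corresponds to 20 M read pairs or 40 M single reads. Gene totals reached 49.5 M, so whether mates or fragments were counted, and how the stated yield relates to the totals, stayed open.

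The tables held 32520 genes, and both tables used the same 6 columns, which were matched to the samples by the labels. Of these genes, 101 had no symbol in the FPKM table, and 84 of the 101 were named from a table of Ensembl symbols. Genes were kept with the filterByExpr function of edgeR 4.0.16 at a minimum count of 10, which left 22347 genes. Counts were scaled by TMM factors and compared between genotypes with the quasi-likelihood test of edgeR (two-sided, robust, genotype as the single term) in R 4.3.3. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. CPM values (counts relative to the scaled library total) were computed from the deposited counts and the TMM factors, and values are given as mean ± SD over 3 pools. Log2 fold changes are bcas2-KO over WT. Counting error alone sets a floor of 3 counts, or 0.0606 to 0.0914 CPM depending on the library, and sequenced PCR products without molecular identifiers are not independent molecules.

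A set of 32 gene lists (complexes, pathways and cell type markers of the larva) was fixed before the data were examined. The lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and p-values were adjusted over the 32 lists. Camera with an estimated correlation and fry were run beside it. The rule for the genes named in the text was fixed at the same time. It always takes bcas2, mdm2, mdm4 and cdkn1a, and a further gene that, with the list holding it, is not reported here. It then takes the 10 highest and 10 lowest fold changes among called genes with a symbol, no overlap of the genotypes and a mean of at least 5 CPM in the higher genotype. It then takes up to 3 members with the smallest p of each list that camera called, and up to 2 members of each other list. Genes outside this rule are marked as chosen after their values were seen.

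Genes on the chromosome of bcas2 were compared with all others by Fisher's exact test (two-sided). Positions came from a RefSeq gene table of the assembly GRCz12tu, which is not the assembly of the counts, so that table was used for gene order only and no coordinates are given. Of the tested genes, 17218 had a place in it. A planned window in megabases was replaced by the 100 nearest genes on each side of bcas2. A planned comparison of intron number with fold change was not analysed here, because it needs an exon annotation of the build used.

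Before use, the gene test was tested on simulated data for the same comparison with 22347 genes, of which 200 were changed. It recovered 31.1% of 61 genes changed 1.5-fold, 67.1% of 73 genes changed 2-fold and 86.4% of 66 genes changed 4-fold. It made 15 false calls, which was 10.7% of all its calls and above the nominal level of 5%. In simulated lists, camera called 3 of 3 raised lists and 0 of the unchanged lists. Those simulated genes varied independently of each other, unlike genes in the libraries.

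Libraries of a genotype were compared before averaging, and a chi-square test over genes gave 13.4 to 36.3 per degree of freedom for the 6 pairs of libraries within a genotype, far above sampling noise, so no library was a copy of another. Per the labels the samples are biological replicates of pooled embryos, while the clutches are not stated. Alternatives were DESeq2 1.42.0, other scalings (RLE, upper quartile, library totals), no filter or a stricter filter on low counts, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and each library left out in turn. A term for gene length, gene windows around bcas2, lists without shared members, and 2 fits that account for eye transcripts in 2 libraries were added after seeing the data.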

Results

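Transcript levels were measured by RNA sequencing in pools of zebrafish embryos at 3 days post fertilization. There were 3 pools of WT embryos and 3 pools of bcas2-KO embryos, with 10 embryos in each pool. Gene counts summed to 49526995, 43210108 and 35560010 in the WT pools and to 39246693, 40462653 and 32822716 in the bcas2-KO pools. The skeletal and cardiac actin gene actc1b took the most counts in every library (4.71% to 5.65%), and the 10 most abundant genes took 18.0% to 20.1%. The first principal component held 48.9% of the variance and placed the 3 WT libraries on one side (-20.8 to -48.9) and the 3 bcas2-KO libraries on the other (34.9 to 39.0). The labels state that the experiment was made to find genes and splicing events that differ between the genotypes. Splicing events were not analysed here.

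The targeted gene was lower in each bcas2-KO library. The gene bcas2 (ENSDARG00000043631) codes for a component of the Prp19 complex of the spliceosome. Its level was 28.2 ± 1.06 CPM in WT and 3.71 ± 0.715 CPM in bcas2-KO (SD, n = 3 pools each), 7.65-fold lower. The counts were 1503, 1189 and 916 in the WT libraries and 146, 125 and 146 in the bcas2-KO libraries. The log2 fold change was -2.94 (SE 0.13, adjusted p = 4.4e-06, edgeR quasi-likelihood test).

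Transcripts of mdm2, which codes for a ubiquitin ligase, were 1.82-fold higher in bcas2-KO, at 42.5 ± 4.06 CPM in WT and 77.3 ± 3.73 CPM in bcas2-KO (log2 fold change 0.86, SE 0.09, adjusted p = 0.00033, edgeR). Those of the related gene mdm4 rose 1.33-fold, from 37.8 ± 3.19 to 50.3 ± 1.99 CPM (adjusted p = 0.0103). The cell cycle inhibitor gene cdkn1a rose 1.48-fold, from 12.8 ± 2.59 to 18.8 ± 1.94 CPM (adjusted p = 0.0297). The mdm4 call was lost without WT library 2 (adjusted p = 0.0501) or bcas2-KO library 1 (0.0510). The cdkn1a call was lost without WT library 2 (0.0837), bcas2-KO library 1 (0.0802) or bcas2-KO library 3 (0.1001), and in the 4 libraries without eye transcripts described further on (0.0917).

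**Figure D1:**
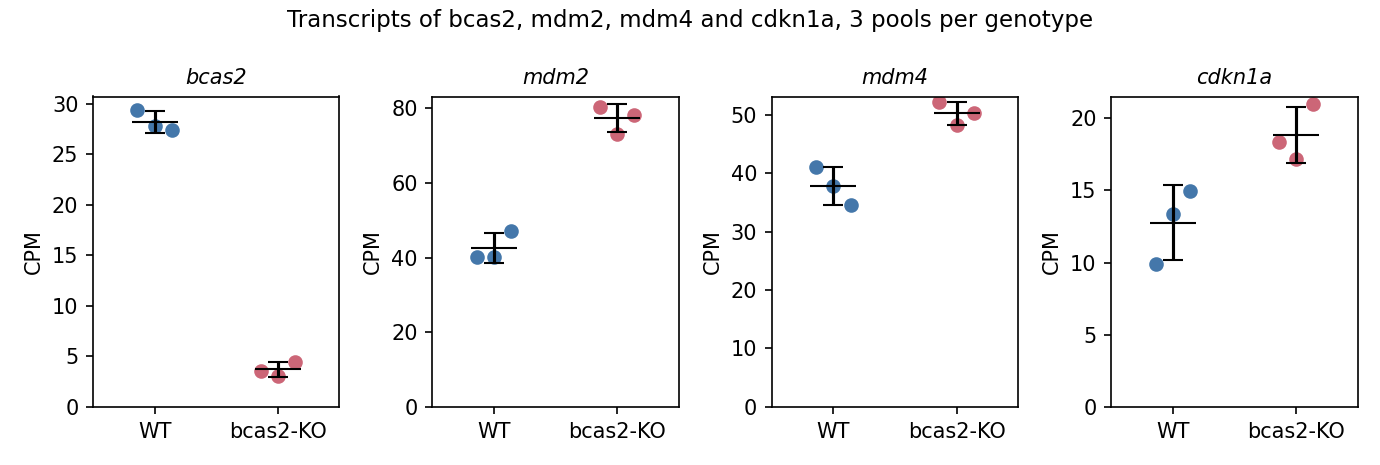
Level of bcas2, mdm2, mdm4 and cdkn1a in CPM (vertical axis, from 0) in the 3 WT and 3 bcas2-KO pools; points are pools, horizontal marks are means and bars are SD. The bcas2-KO pools lie at 3.71 CPM on average for bcas2 against 28.2 CPM in WT, and at 77.3 CPM for mdm2 against 42.5 CPM.

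Across all genes, 2369 were higher and 2013 lower in bcas2-KO, together 19.6% of the 22347 tested. Lower genes made up most of the strong changes: 271 genes were at least 2-fold higher and 556 at least 2-fold lower. The values of the genotypes did not overlap in 39.4% of tested genes, against 10% by chance for 3 against 3. The median fold was 1.42 for genes that rose and 1.59 for genes that fell. The split by direction moved with the scaling: upper-quartile factors gave 1746 higher and 2625 lower genes, 39.9% higher against 54.1% with TMM factors. The number of calls fell to 1730 without WT library 2, 1974 without bcas2-KO library 1 and 2491 without bcas2-KO library 3, was 2942 without WT library 3 and 3067 without bcas2-KO library 2, and rose to 5171 without WT library 1. A call kept by any of these fits never changed sign.

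Among called genes that met the rule for named genes, with at least 5 CPM on average in the higher genotype, the 10 highest fold changes lay between 4.23-fold and 6.69-fold. Transcripts of snapc4, which codes for a subunit of the complex that activates snRNA promoters, rose 5.81-fold, from 7.45 ± 0.452 to 43.3 ± 3.49 CPM (log2 fold change 2.54, SE 0.10, adjusted p = 2.8e-06, edgeR). Transcripts of ice1, a part of the little elongation complex at snRNA genes, rose 4.96-fold, and those of brf2, an RNA polymerase III factor, rose 4.45-fold. Transcripts of mettl16, which codes for the methyltransferase of U6 snRNA, rose 4.59-fold, from 6.28 ± 0.406 to 28.9 ± 0.465 CPM. The others of these 10 were nhsa (6.69-fold), fmnl2b (5.38-fold), zmynd8 (4.86-fold), dgcr2 (4.68-fold), rictorb (4.44-fold) and ube3c (4.23-fold), with adjusted p from 2.8e-06 to 0.00112.

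The genes with the lowest fold changes under the same rule, apart from bcas2, included digestive enzymes of the pancreas. The elastase gene ela2 fell from 9.67 ± 3.25 to 0.298 ± 0.0229 CPM (log2 fold change -5.01, SE 0.29, adjusted p = 2.4e-05, edgeR). The elastase gene cela1.6 fell from 32.5 ± 5.46 to 4.08 ± 0.315 CPM, and ctrl and cel.2 had log2 fold changes of -2.54 and -2.29. The mucin gene muc5.3 (-2.26), the cytochrome P450 gene cyp3a65 (-2.08) and the histone gene hist2h3c (-3.52) fell as well. The histone gene hist2h3c and the myosin gene myhz1.1 (-2.01) belong to families of similar genes, and how reads that match several copies were counted is not given in the sources used here, so their values are uncertain. The heat shock gene hsp70l had 30.7 CPM in WT library 3 against 10.4 and 11.6 CPM in the other WT libraries, and 1.88 to 4.09 CPM in bcas2-KO. Its call (log2 fold change -2.55, adjusted p = 0.0414) was lost without WT library 2 (adjusted p = 0.0777), without bcas2-KO library 1, 2 or 3 (0.0912, 0.142 and 0.114) and in the 4 libraries without eye transcripts (0.101), that of myhz1.1 without WT library 2 or bcas2-KO library 1, 2 or 3 (0.0822, 0.0802, 0.0888 and 0.0768), and that of cyp3a65 without WT library 3 (0.0659) or bcas2-KO library 1 (0.0579).

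Transcripts for the machinery of splicing rose in bcas2-KO. In the list of core snRNP proteins, 36 of 51 members rose, 0 fell and 15 did not pass, and 38 rose when adjusted over the list alone. The median log2 fold change of the list was 0.48 (camera adjusted p = 1.2e-22, adjusted p = 0.534 with an estimated correlation). The gene prpf8, for the central U5 protein, rose 2.77-fold from 149 ± 12.96 to 413 ± 20.7 CPM. The helicase gene snrnp200 rose 2.48-fold, from 99.1 ± 6.66 to 246 ± 4.32 CPM, and lsm7, for a part of the ring on U6 snRNA, rose 2.86-fold. Among SR and hnRNP splicing regulators, 25 of 46 rose, 2 fell and 19 did not pass, with 29 higher and 2 lower when adjusted over the list alone. Their median was 0.34 (camera adjusted p = 2.9e-09, adjusted p = 0.619 with an estimated correlation). The kinase gene clk2a rose 1.86-fold, hnrnpa0a 1.72-fold and srrm2 1.61-fold. In the Prp19 complex and its partners, without bcas2, 9 of 18 rose, 2 fell and 7 did not pass, with 10 higher and 2 lower when adjusted over the list alone (median 0.28, camera adjusted p = 0.00184, adjusted p = 0.534 with an estimated correlation). The helicase gene aqr rose 2.07-fold, isy1 2.01-fold and xab2 1.87-fold, while ctnnbl1 (log2 fold change -0.40) and ppil1 (-0.34), chosen after their values were seen, fell.

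**Figure D2:**
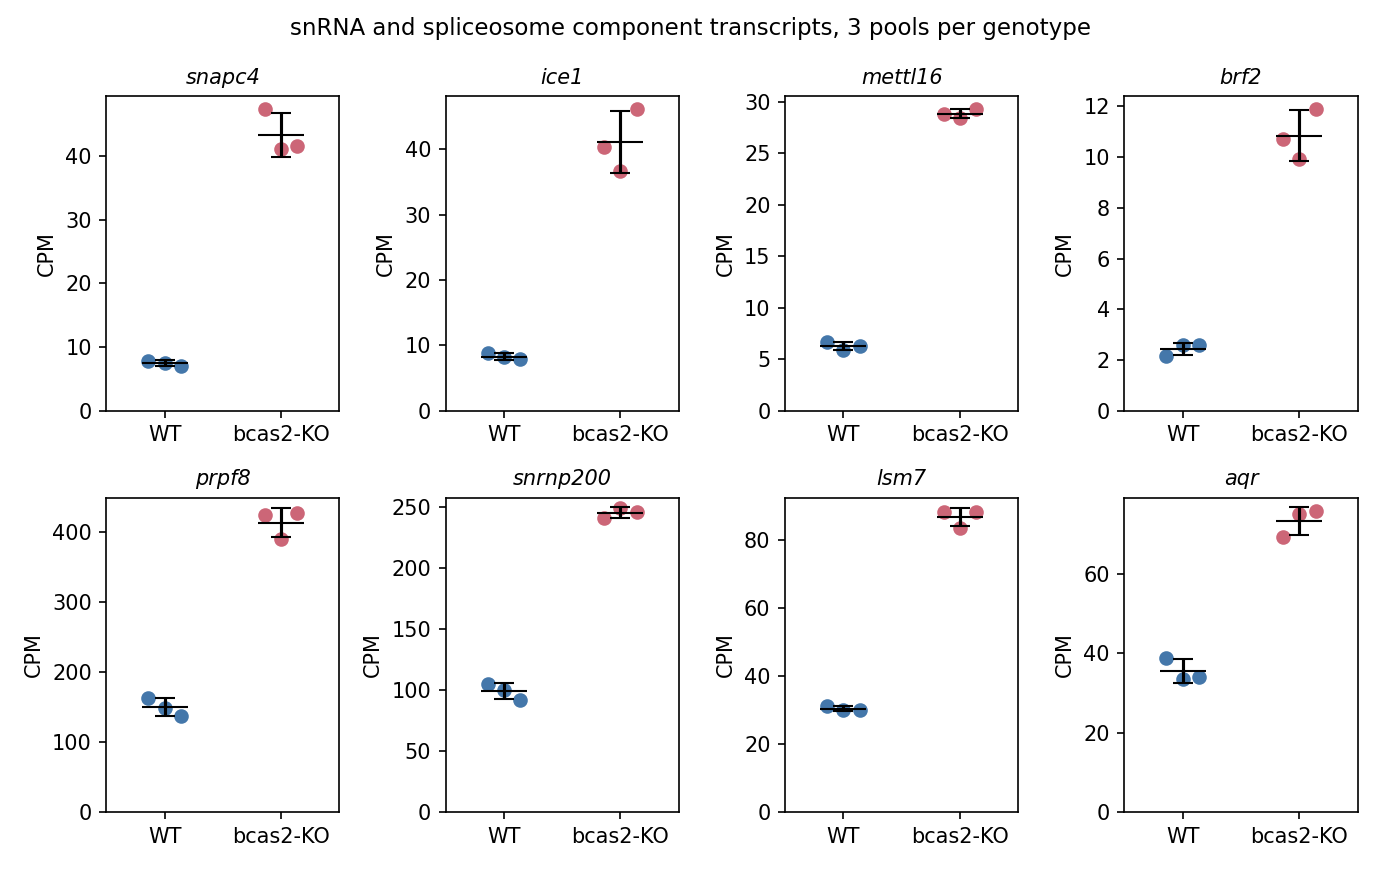
Level in CPM (vertical axis, from 0) of 4 genes for snRNA production or modification (snapc4, ice1, mettl16, brf2) and 4 spliceosome genes (prpf8, snrnp200, lsm7, aqr) in each pool; points are pools, horizontal marks are means and bars are SD. In all 8 genes each bcas2-KO pool lies above each WT pool, as for prpf8 at 413 against 149 CPM on average.

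Markers of several tissues fell. In the exocrine pancreas list, 15 of 16 measured members fell and 0 rose, the same when adjusted over the list alone. The median log2 fold change was -1.85 (camera adjusted p = 4.3e-13, adjusted p = 0.534 with an estimated correlation). The chymotrypsinogen gene ctrb1 fell from 45.8 ± 5.24 to 11.4 ± 2.52 CPM, and the member that did not pass was the transcription factor gene ptf1a, at a low level of 0.545 and 0.525 CPM. Which cells these ptf1a transcripts came from was not tested. In cartilage and bone, 12 of 24 fell and 0 rose, with 15 lower when adjusted over the list alone (median -0.54, camera adjusted p = 3.6e-07, adjusted p = 0.534 with an estimated correlation). The collagen gene col9a3 fell from 534 ± 32.1 to 338 ± 15.3 CPM, col11a2 from 723 ± 78.9 to 438 ± 25.9 CPM, and cnmd from 159 ± 8.91 to 109 ± 2.63 CPM. In skin epithelium, 12 of 22 fell and 0 rose, with 15 lower when adjusted over the list alone (median -0.45, camera adjusted p = 1.1e-06, adjusted p = 0.534 with an estimated correlation), with icn at -0.61, krt92 at -0.71 and cyt1l at -0.62.

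Among markers of neutrophils and macrophages, 6 of 23 fell and 0 rose, the same when adjusted over the list alone (median -0.45, camera adjusted p = 0.00016, adjusted p = 0.619 with an estimated correlation). The myeloperoxidase gene mpx fell from 71.5 ± 14.0 to 32.1 ± 4.50 CPM and lcp1 had a log2 fold change of -0.76, while cpa5 (-1.47) is also in the pancreas list. Among interferon response genes, 4 of 14 fell and 1 rose, with 5 lower and 1 higher when adjusted over the list alone (median -0.68, camera adjusted p = 0.0120, adjusted p = 0.619 with an estimated correlation), with isg15 at -1.99, mxc at -1.28 and ifi45 at -1.81. In this list stat1b had 9.87 CPM in WT library 3 and 1.04 and 1.71 CPM in the other WT libraries. In endothelium, 6 of 20 fell and 0 rose, with 8 lower when adjusted over the list alone (median -0.20, camera adjusted p = 0.0203, adjusted p = 0.619 with an estimated correlation), with stab1 at -0.65, plvapa at -1.03 and kdrl at -0.31. The endothelium call was lost without WT library 2 (adjusted p = 0.0605) or bcas2-KO library 1 (0.0619). In oligodendrocytes and glia, 5 of 12 fell and 0 rose, with 7 lower and 1 higher when adjusted over the list alone (median -0.35, camera adjusted p = 0.0301, adjusted p = 0.534 with an estimated correlation), with glula at -0.52, slc1a2b at -0.39 and cldnk at -0.44, and the call was lost without WT library 1 (0.0761). In the hatching gland list, agr2 (-1.45) fell, 8 of 9 members did not pass and the same was found when adjusted over the list alone (median -2.29, camera adjusted p = 0.0391, adjusted p = 0.619 with an estimated correlation). The hatching enzyme gene he1.1 had 39.6 CPM in WT library 2 and 0.123 to 6.52 CPM elsewhere, and the list had a median of -0.67 without that library (adjusted p = 0.194). That call was also lost without WT library 1 (0.0761) or bcas2-KO library 3 (0.1397).

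In the Notch pathway, 5 of 29 members rose and 0 fell, with 6 higher when adjusted over the list alone (median 0.21, camera adjusted p = 0.0121, adjusted p = 0.619 with an estimated correlation), among them the ligand gene jag1b (1.38-fold), her6 (1.35-fold) and rbpja (1.29-fold). The call was lost without WT library 1 (0.0669) or bcas2-KO library 2 (median 0.12, 0.166).

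**Figure D3:**
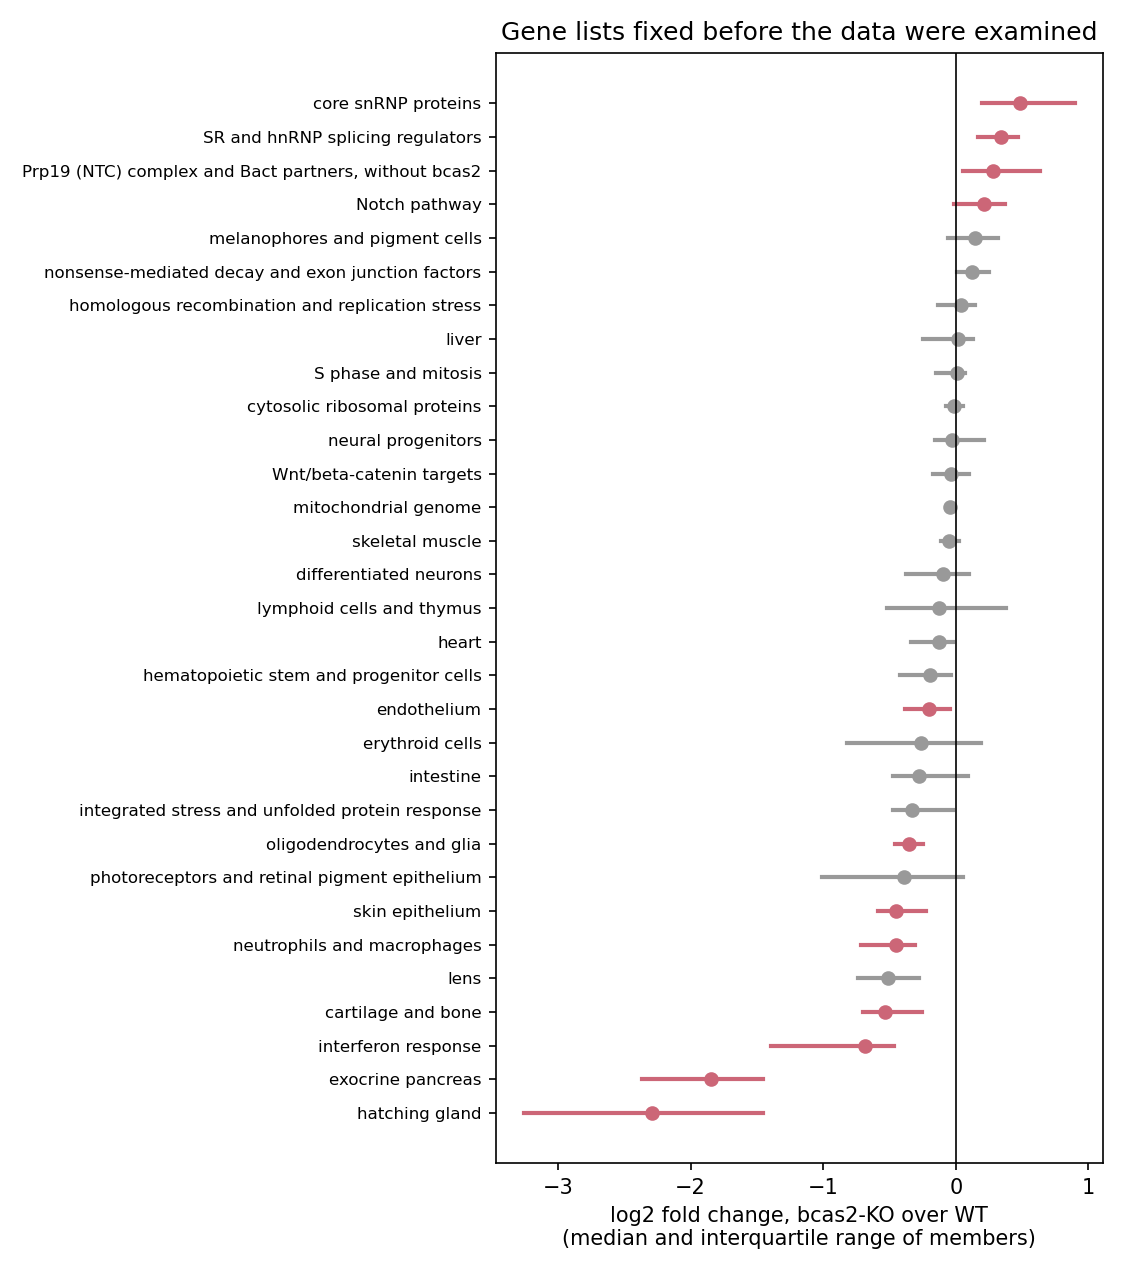
Median log2 fold change of bcas2-KO over WT (horizontal axis) of the tested members of each of 31 gene lists, with lines for the interquartile range; red marks the 12 lists called by camera at the preset correlation and grey the others. The exocrine pancreas has a median of -1.85 and the core snRNP proteins have a median of 0.48.

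The other 19 lists reported here did not pass. In erythroid cells 7 of 26 fell and 1 rose (median -0.26, camera adjusted p = 0.0633), and the embryonic globin genes hbbe1.1 and hbbe2 had log2 fold changes of -1.04 and -1.06. When a library was left out, the erythroid median ranged from -0.35 without WT library 3 to -0.15 without bcas2-KO library 3. It was -0.093 in the 4 libraries without eye transcripts. Among nonsense-mediated decay and exon junction factors 4 of 16 rose and 1 fell (adjusted p = 0.0686), with eif4a3 at 0.47 and casc3 at 0.37. In the integrated stress and unfolded protein response 4 of 21 fell and 1 rose (adjusted p = 0.0686), with sesn2 at -0.85 and atf4a at -0.38. Among hematopoietic stem and progenitor cell genes 2 of 14 fell and 1 rose (adjusted p = 0.159), with runx1 at -0.68 and gfi1aa at 0.93. In heart 2 of 14 fell (adjusted p = 0.159), with tnnt2a at -0.66 and myl7 at -0.48. In differentiated neurons 6 of 30 fell and 3 rose (adjusted p = 0.247), with gap43 at -0.47 and cplx2 at -0.66, and in neural progenitors 3 of 28 fell and 1 rose (adjusted p = 0.959), with fabp7a at -0.79 and ascl1b at -1.09. The symbols cplx2 and ascl1b, like myhz1.1 above, are each shared by more than 1 Ensembl gene, and each value given is of a single one. In intestine 3 of 18 fell and 1 rose (adjusted p = 0.274), with elovl2 at -1.19 and vil1 at -0.49. In pigment cells 1 of 15 fell (adjusted p = 0.336), tyrp1a at -0.46. In skeletal muscle 4 of 31 fell and 1 rose (adjusted p = 0.432), with acta1a at -0.59 and myog at 0.66.

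In the S phase and mitosis list 5 of 39 fell and 4 rose (adjusted p = 0.795), with pcna at -0.42 and dut at -0.40. In homologous recombination and replication stress 3 of 32 fell and 1 rose (adjusted p = 0.959), h2ax at -0.95 and fancg at 1.13. Among cytosolic ribosomal proteins 3 of 80 fell and 2 rose (adjusted p = 0.909), with rps20 at -0.42 and rpl9 at 0.93. The level of rpl9 was only 2.97 CPM in WT and 5.67 CPM in bcas2-KO, against 658 and 491 CPM for rps20. How well the counts of rpl9 measure that gene was not tested. In the Wnt target list 3 of 14 rose and 1 fell (adjusted p = 0.795), with notum1a at 0.54 and znrf3 at 0.51. In lymphoid cells 1 of 10 rose (adjusted p = 0.959), tox at 0.38. In liver 1 of 22 fell, ahsg2 at -1.87 from a level of 0.505 CPM, and the median was 0.02 (adjusted p = 0.972). In the mitochondrial genome 0 of 13 changed by edgeR and 0 by DESeq2, and 0 had an unadjusted p under 0.05 (median -0.04, camera adjusted p = 0.795). Over these 19 lists, eye lists included, 24 members rose and 46 fell, and 23 rose and 46 fell when adjusted over the list alone. The median and the camera direction differed in sign for the Wnt target, lymphoid, S phase and homologous recombination lists, and median and mean for the Wnt target, S phase, homologous recombination, liver and ribosomal protein lists. Without WT library 3, camera called erythroid cells (adjusted p = 0.00104), neurons (0.0355), heart (0.0443) and intestine (0.0385). Without bcas2-KO library 2 it called erythroid cells (0.0240) and nonsense-mediated decay (0.0471), and without bcas2-KO library 1 the stress response (0.0377).

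Eye transcripts differed between libraries of the same genotype. In the lens list 0 of 9 tested members changed by edgeR, 0 by DESeq2 and 0 at an unadjusted p under 0.05 (median log2 fold change -0.51, camera adjusted p = 0.708), and in photoreceptors and retinal pigment epithelium 0 of 26 changed by edgeR, 0 by DESeq2 and 2 at an unadjusted p under 0.05 (median -0.39, adjusted p = 0.711). The lens gene crybb1 had 71.6 CPM in WT library 1 and 73.1 CPM in bcas2-KO library 3, and 0.0247 to 0.449 CPM in the other 4 libraries. The cone opsin gene opn1sw1 had 27.7 and 22.1 CPM in those 2 libraries and at most 0.389 CPM in the others. The neuronal gene elavl3 had 134 to 171 CPM in all 6 libraries. The genes shown in the plot of eye and neuronal transcripts were chosen after their values were seen. Without bcas2-KO library 3 the lens list was called lower (median -5.14, adjusted p = 0.0227) and so was the photoreceptor list (median -2.26, adjusted p = 0.0107). Without WT library 1 both medians were positive and not called (lens 3.43, adjusted p = 0.585; photoreceptors 1.16, 0.313), and without bcas2-KO library 1 or 2 they lay between -0.00182 and 0.134. In the 4 libraries with a lens list median under 1 CPM, 2055 genes were higher and 1604 lower in bcas2-KO, and with a term for eye transcripts in all 6 libraries 2388 were higher and 2085 lower. With that term the lens list, from which the term was defined, was called lower (adjusted p = 0.0330). In those 4 libraries, 2 per genotype, the glia and hatching gland lists were no longer called (adjusted p = 0.126 and 0.264), with medians of -0.353 and -2.03 against -0.351 and -2.29 in all 6. The genes hbbe1.1, gfi1aa, tox, kdrl, tnnt2a, myl7, znrf3 and ifi45 were not called there either (0.0545 to 0.138). Their log2 fold changes were larger in kdrl (-0.33 against -0.31) and ifi45 (-2.06 against -1.81). They were smaller in hbbe1.1 (-0.95 against -1.04), gfi1aa (0.79 against 0.93), tox (0.32 against 0.38), tnnt2a (-0.49 against -0.66), myl7 (-0.43 against -0.48) and znrf3 (0.37 against 0.51). Of the lost calls described earlier, cdkn1a had a smaller log2 fold change there (0.33 against 0.56) and hsp70l a similar one (-2.58 against -2.55). With fewer libraries a call can be lost at the same fold, but many of these folds were smaller too. The losses therefore neither show nor exclude an effect of eye transcripts.

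**Figure D4:**
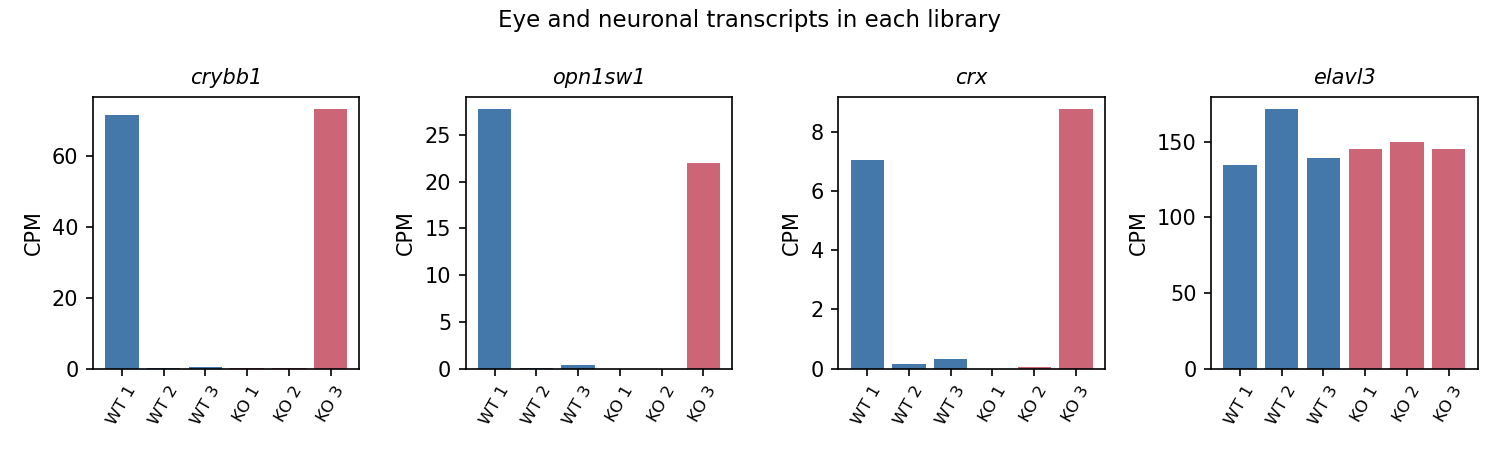
Level in CPM (vertical axis, from 0) of the lens gene crybb1, the cone opsin gene opn1sw1, the photoreceptor transcription factor gene crx and the neuronal gene elavl3 in each library; blue bars are WT and red bars are bcas2-KO libraries. WT library 1 and bcas2-KO library 3 hold 71.6 and 73.1 CPM of crybb1 and the other 4 at most 0.449 CPM.

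Embryos sorted by genotype also differ in the chromosome region around the mutation, so calls near bcas2 were counted. On the chromosome of bcas2, 167 of 768 tested genes (21.7%) were called, against 3420 of 16450 (20.8%) on the others, an odds ratio of 1.06 (95% interval 0.883 to 1.26, Fisher's exact test, two-sided, p = 0.525). Among the 100 nearest genes on each side of bcas2, 46 of 200 were called (odds ratio 1.14, Fisher's exact test, two-sided, p = 0.432), with a 95% interval of 0.798 to 1.59. The odds ratio was 1.34 for the 50 nearest (0.820 to 2.12) and 1.21 for the 200 nearest (0.932 to 1.56).

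With an estimated correlation between genes, camera called 0 of 32 lists, and 2 had an unadjusted p under 0.05. By fry, which tests whether the genes of a list move on balance in 1 direction, the neutrophil and macrophage (adjusted p = 0.0808), interferon (0.0865), endothelium (0.0579), hatching gland (0.148) and Notch (0.198) lists were not called, while nonsense-mediated decay factors (0.0373, higher) and hematopoietic stem and progenitor cell genes (0.0373, lower) were.

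Calls of single genes named here that were lost without a library had adjusted p from 0.0501 to 0.142 there. Of those not yet described, myl7, cldnk and slc1a2b lost the call in 5 of the 6 fits without a library. The genes ahsg2, gfi1aa, ifi45, kdrl, rbpja, tox and tyrp1a lost it in 4 and atf4a and vil1 in 3. The genes ascl1b, casc3, rps20 and runx1 lost it without WT library 2 and without bcas2-KO library 1. The genes glula, her6 and myog lost it without WT library 2, mxc and sesn2 without bcas2-KO library 1, and znrf3 without bcas2-KO library 3. Of the genes that lost the call in 3 or more fits, myl7 lost it without each library but WT library 3, and cldnk and slc1a2b without each but WT library 1. In ifi45 it was lost without WT library 2 or any bcas2-KO library, in ahsg2 without WT library 2 or 3 or bcas2-KO library 1 or 2, and in rbpja without these same libraries. In gfi1aa, kdrl, tox and tyrp1a it was lost without WT library 2 or 3 or bcas2-KO library 1 or 3, and in atf4a and vil1 without WT library 2 or bcas2-KO library 1 or 3.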

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

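The log2 fold change of bcas2 stayed between -3.09 and -2.80 in every fit run. Of 84 called genes among the 95 named, 29 lost the call in at least 1 setting, 27 of them when a library was left out, and 0 changed direction. Leaving out a library gave 1013 to 2813 higher and 717 to 2358 lower genes (5171 in all without WT library 1), and the cause was not tested. An adjusted p under 0.01 left 953 higher and 597 lower genes, and a change of at least 2-fold 271 and 556. DESeq2 gave 2568 higher and 2148 lower genes. Camera with an estimated correlation called 0 lists higher and 0 lower (2 lists at an unadjusted p under 0.05), where fry called 4 higher and 5 lower and did not call 5 of the 12 lists, and 8 of the 12 lists kept their call in each fit without 1 library. Whether replicate numbers pair the samples stayed unclear. Correlations of same-numbered deviations were -0.143, 0.375 and 0.0134, and not every sample correlated best with its own number. With the replicate block 2604 genes were higher and 2318 lower, the erythroid (adjusted p = 0.0321) and stress response (0.0262) lists were called lower, and hsp70l (0.148) and tox (0.0533) lost the call, while he1.1 (0.000692), tyr (0.0287) and vtnb (0.0161) gained it. The direction of bfsp2 rested on WT library 1 (6.22 CPM, against 0.492 and 0.778 in the other WT libraries): it ranged from -1.87 to 1.01 on the log2 scale when a library was left out, positive without WT library 1, and was 0.16 in the 4 libraries without eye transcripts, which were defined by lens genes. Values near 0 turned too: mt-nd4 ranged from -0.17 to 0.0059, positive without WT library 2, and mt-nd4l from -0.12 to 0.0194, positive without WT library 2 or bcas2-KO library 3, and was 0.0731 with the gene length term. Medians of 11 lists not called in the fit as reported changed sign in some fits. When a library was left out, lens ranged from -5.14 to 3.43 and photoreceptors from -2.26 to 1.16, each lowest without bcas2-KO library 3 and highest without WT library 1. The other ranges were S phase -0.0654 to 0.0808, homologous recombination -0.0336 to 0.0629, neural progenitors -0.113 to 0.153, skeletal muscle -0.115 to 0.0348, liver -0.0343 to 0.0938, Wnt targets -0.0606 to 0.0512, ribosomal proteins -0.0306 to 0.0379 and the mitochondrial genome -0.118 to 0.0354. With library totals neural progenitors had 0.00251 and ribosomal proteins 0.0271. With the gene length term S phase had -0.0145, ribosomal proteins 0.0552 and the mitochondrial genome 0.0584. In the 4 libraries without eye transcripts intestine had 0.0563 and Wnt targets 0.0538. The odds ratio for the chromosome of bcas2 ranged from 0.957 to 1.204 when a library was left out, and was 0.914 in the 4 libraries without eye transcripts; the cause was not tested. With 50 or 200 genes on each side of bcas2 the odds ratio was 1.34 and 1.21. The intron comparison with its alternatives and the windows in megabases were not run. In the simulated data 31.1% of 61 genes changed 1.5-fold were recovered, so a changed gene can be missed and a missing call does not show an unchanged gene. Only 200 genes were changed in that simulation, while 4382 were called in the data. The recovery with as many changed genes as in the data was not tested, so 31.1% does not measure the recovery in these libraries. The length, window, shared-member and eye settings were chosen after seeing the data.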

Other observations

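The tests of gene length, library scaling, the liver list, a common source of eye RNA, the snRNA genes, the U4/U6.U5 tri-snRNP components and the neighbours of bcas2 were chosen or given their bounds only after the results were seen, as were the fits without eye transcripts and the bound used with them, while the tests of the splits and of further eye markers were written down before their values were seen.

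For the count of changed genes, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many genes as the genotypes, which was the genotype split itself. The real value was 4382 genes and the highest of the other splits 0 by edgeR at an adjusted p under 0.05. For gene lists, 6 of the 10 splits gave 12 or more called lists, and the highest of the other splits gave 16 against 12 for the genotypes. With 10 splits no share under 0.05 can be reached in either case. Each other split sets 2 WT libraries and 1 bcas2-KO library against 1 WT library and 2 bcas2-KO libraries, so it keeps part of the genotype difference and adds the rest to the spread within groups. The lists called in those splits can therefore carry the genotype difference itself, and few called genes follow from the design, so the splits limit neither the list calls nor the gene calls.

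The rise of spliceosome transcripts was weighed against 2 technical explanations. A trend with gene length was argued against: with a term for gene length the median log2 fold change of the core snRNP list was 0.56, and 38 of its 51 members rose. The choice among 4 scalings of the libraries did not remove the rise. The median of the list was lowest with upper-quartile factors, at 0.42. Its SE of 0.0874 takes members as independent and does not measure the spread over pools. At least 35 of the 51 members were called higher under each scaling, while upper-quartile factors changed 1235 calls among all genes. The 4 scalings moved the median of all genes only between -0.079 and 0.021, and all are computed from the counts themselves. Scalings further apart were not tried, so a larger error of scaling was not tested. A response of transcripts for splicing factors to the loss of bcas2 may be behind the rise, a hypothesis that was not tested, since intron retention and splicing were not analysed here.

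The fall of pancreas, cartilage, skin and leukocyte transcripts had a median log2 fold change of -0.50 over these 4 lists. The median was -0.53 in the 4 libraries without eye transcripts, so the fall does not rest on the libraries that hold them. Eye transcripts were high in WT library 1 and bcas2-KO library 3, so both genotypes held them and leaving them out could hardly move the median. Uneven content of other tissues in the pools was not tested by this and stays open. A trend with gene length was argued against by a median of -0.46 with a length term. The liver list did not share the fall in its median, which was 0.0206, while its mean was -0.13. The SE of that median, 0.0496, takes members as independent and does not measure the spread over pools. The genes of that 1 list thus did not fall like those of the 4 lists. Whether other tissues express them was not tested, so the liver list does not decide on a delay of all late tissues. It does not show whether the liver developed on time. A delay of all or some tissues, fewer cells of these types and lower levels per cell stay open, and pooled embryos cannot separate them.

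The difference in eye transcripts between WT library 1 and bcas2-KO library 3 and the other 4 libraries may come from different amounts of eye tissue. There may be more of it in these 2 pools or less in the other 4. In the other 4 libraries crybb1 had 1 to 15 counts and opn1sw1 had 0 to 13, so these transcripts were nearly absent there. Whether those 4 pools represent whole embryos is therefore in doubt. What each pool held cannot be told from these values, which also limits the marker lists of other tissues. The test of different amounts of eye tissue that was written beforehand did not reach its bound. For 22 further retina and lens markers the median log2 ratio between the 2 libraries and the other 4 was 0.47. This lay under the bound of 1 by more than its SE of 0.201, which by that test counted against the explanation. That SE takes markers as independent and does not measure the spread over pools. That bound was set without regard to markers that other tissues may express, which was not tested. Of the 11 markers under 1 CPM in each of the other 4 libraries, 9 had a ratio above 1, and of the 11 with higher levels there, 0 did. This division was made after the values were seen and by the level in the same 4 libraries that the ratio is taken against. It therefore cannot rescue the explanation, which is neither supported nor excluded. A single common source of foreign eye RNA stays open as well. The ratio of WT library 1 to bcas2-KO library 3 lay between 0.806 and 1.85 in 18 of 21 eye genes (median 1.28), and bfsp2 (2.53), saga (3.90) and rho (4.41) departed from it. The chi-square per degree of freedom of 82.2 over these genes grows with their counts, and pairs of replicates were not compared at like counts, so it does not decide.

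The 4 genes for snRNA production or modification among the 10 highest named genes led to the hypothesis that others of this kind rose too. Among the 38 remaining genes of a list made after the values were seen, and leaving out ssb and ints1, 9 rose and 2 fell, with a median log2 fold change of 0.17. Camera gave p = 0.00398 at the preset correlation and p = 0.098 with an estimated correlation, so the data do not settle it. A second hypothesis was that tri-snRNP components rose more than U1 and U2 components. The mean log2 fold change was 0.76 for 20 tri-snRNP genes and 0.38 for 19 U1 and U2 genes, a difference of 0.38 (permutation test over genes, 100000 draws, two-sided, p = 0.0111). Genes are not independent replicates and the classes were drawn from the same data, so this difference may not hold elsewhere. A haplotype effect on neighbours of bcas2 stays open: the odds ratio for the 100 nearest genes on each side was 1.137 with an upper limit of 1.59, too wide to exclude it.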
